A study of Mus musculus with 6 samples.

How the data were processed

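The series holds 6 RNA-seq libraries of the distal part of the left sciatic nerve of C57BL/6 mice, 3 from females and 3 from males. Per the labels' protocols, the mice were 6 to 8 weeks old, nerves were collected 24 h after surgery, with all procedures done in the morning, tissue of 2 animals was pooled for each library, and 500 ng of total RNA with an integrity number of at least 7.0 went into each stranded, poly-A selected library. Paired reads of 100 nt were collected to the depth the study set as its minimum, per the labels' protocols. The sex in the labels set the 2 groups. The labels disagree on the surgery: a treatment field calls all 6 libraries axotomy, as does the design text, while the written procedure for the same libraries describes exposing the nerve without cutting it.

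The submitters' processing notes name Trimmomatic 0.39, Salmon 1.5.2 and MultiQC 1.9. The deposited table of each library gives, per the file headers, an estimated count of reads and a TPM value (abundance scaled to a fixed total) for each of 140789 transcripts, with the transcript's length and effective length. The estimated counts were not normalized by the authors. TPM values were deposited as Salmon computed them from the estimated counts and effective lengths, per the file headers. Transcript names carry gene IDs and symbols. The genome build and the annotation release behind them are not given in the sources used here, so no coordinates are printed. Salmon shares reads between similar transcripts by an estimate, so counts of near-identical genes are uncertain. Whether strand was used in counting is not given in the sources used here.

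From these tables, the estimated counts of a gene's transcripts were summed over 54309 genes and rounded to whole numbers. Chromosomes came from the GENCODE M21 annotation of the mouse genome by gene ID, which matched 94.8% of the genes. Genes with low counts were left out with edgeR's filterByExpr, which kept 19129 genes, 18450 of them autosomal. Libraries were scaled by TMM, and female was compared with male by edgeR's quasi-likelihood test with robust estimation and no covariate. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05, and all adjusted p-values of single genes below are from this test unless another tool is named. Log2 fold changes are female minus male, with the standard error (SE) taken from the test. Levels are TMM-scaled CPM, as mean ± SD over 3 libraries.

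Before the data were examined, 31 gene lists were fixed for the cell types and processes of an injured nerve, along with the tests and the rule for naming genes. Lists were tested by limma's camera on voom values with the inter-gene correlation preset to 0.01, adjusted over 29 lists; the lists of Y-linked genes and of X-linked genes that escape inactivation were left out of that adjustment. Each test was repeated with a correlation estimated per list and with fry. Members of a list were also counted after adjustment over the list alone. The naming rule took the detected members of both sex-linked lists, the 10 autosomal genes per direction with the largest changes past the threshold at a mean CPM of at least 1, up to 4 members of smallest p per called list, and 15 reference genes. Results of a few genes that the rule names are not reported here. Genes outside it were chosen after their values were seen.

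Libraries held 55272138 to 77610593 estimated reads, so that 3 reads, the limit a count of 0 allows, correspond to at most 0.0543 CPM in any library. These limits cover counting error only. Replicates came from separate pools of animals, per the labels' protocols. No pair of libraries agreed within sampling noise: a chi-square test over genes with at least 20 reads gave at least 26.3 per degree of freedom. The common biological coefficient of variation was 0.183. The gene test was tested on simulated counts of 19129 genes with 200 changed genes. It recovered 25.4% of genes changed by 0.5 on the log2 scale, 83.6% of those changed by 1 and 98.5% of those changed by 2, and called 11 unchanged genes. In the same simulation DESeq2 called 155 of the 200 changed genes and 60 unchanged ones, against 138 and 11 for edgeR. A list whose members shared a library shift with no sex effect was also simulated 40 times. Its unadjusted camera p was under 0.05 in 55% of them with the preset correlation and in 10% with an estimated one. List calls below use the adjusted p, a stricter rule whose rate was not taken in these simulations. With the preset correlation that rule still called 10 to 17 lists in the other splits of the 6 libraries into 3 and 3, against 12 for the sexes.

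The alternatives were other scalings, no filter or a stricter one, a length offset, the replicate number as a block, each library left out in turn, DESeq2, limma-voom, limma on log2(TPM + 1), and a minimum of 1.2-fold. After the data were seen, 4 more were added: leaving out the 2 libraries with skeletal muscle transcripts, doing so with an estimated correlation, a muscle covariate, and edgeR without robust estimation. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, BLAST 2.17.0 and Python 3.11.15.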

Results

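RNA was measured in the distal sciatic nerve of female and male mice 24 h after surgery on the nerve. The stated aim was to find molecular signatures that differ between the sexes after axotomy, the cutting of the nerve. The labels name axotomy as the treatment of all 6 libraries, but the procedure written for them describes exposure of the nerve without transection, so the injury state of these nerves is left open here. Each sex had 3 libraries, each pooled from 2 animals. Female libraries 1 to 3 held 72221135, 68696023 and 75159187 estimated reads, and male libraries 1 to 3 held 77610593, 60952331 and 55272138. Every comparison below is of female with male nerves after the same labelled surgery, and nerves of unoperated mice were not analysed here.

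Male nerves had higher RNA levels of complement component C7, of Aldh1a2, Angptl7 and A2m, and of the MHC class II chaperones H2-DMa and H2-DMb1. C7, a part of the membrane attack complex, was at 80.0 ± 25.2 CPM in males and 5.96 ± 1.28 CPM in females (SD, n = 3 each), a log2 fold change of -3.75 (SE 0.29). Hmga2, which encodes a chromatin protein of growing cells, was the 1 autosomal gene that was higher in females, at 11.4 ± 0.624 against 5.90 ± 0.721 CPM. The sex chromosome genes divided the libraries as labelled: Xist stood at 776 ± 108 CPM in females and 1.39 ± 1.84 CPM in males, and Ddx3y at 0.0568 ± 0.0869 CPM in females and 82.1 ± 5.84 CPM in males.

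In all, 21 of 19129 genes passed the threshold in edgeR's quasi-likelihood test, 3 higher in female and 18 higher in male nerves. Among autosomal genes, 1 was higher in female and 13 were higher in male nerves. Aldh1a2, which makes retinoic acid, was at 20.7 ± 1.52 CPM in females and 42.2 ± 1.87 CPM in males. Angptl7, an angiopoietin-like secreted protein gene, had a log2 fold change of -1.18, and the protease inhibitor genes A2m and Serpine2 had -1.10 and -0.85. Lamc3, a laminin chain gene, had a log2 fold change of -1.77, Mfap4, which encodes a microfibril protein, one of -1.12, and Fmod, which encodes a collagen-binding proteoglycan, one of -0.79. Crispld2, a secreted protein gene, had a log2 fold change of -0.92, and Cd209a, a lectin gene of dendritic cells, one of -1.32. The remaining autosomal gene higher in male nerves was Rdh9 (-3.80), which lies outside the naming rule and was chosen after its values were seen; it shares nearly all of its sequence with Rdh16f1, so its own level is uncertain. Adjusted p over the autosomal genes past the threshold ran from 0.00413 for Aldh1a2 to 0.0444 for Lamc3. The count of autosomal genes higher in male nerves was 2, 5 and 178 without female 1, 2 and 3, and 7, 0 and 2 without male 1, 2 and 3. Hmga2 was called only with all 6 libraries or without female 3 among these fits, and DESeq2 called 204 autosomal genes higher in female and 599 higher in male nerves.

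**Figure D1:**
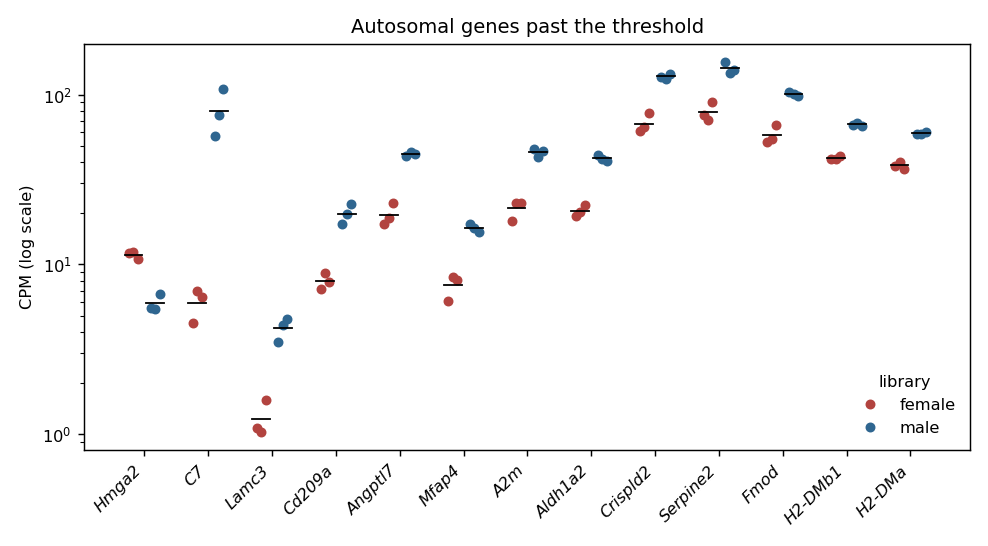
CPM (log scale) of the autosomal genes past the threshold, Rdh9 excepted, in each of 3 female and 3 male libraries (points), with group means (lines). Hmga2 lay higher in all 3 female libraries, and C7 ranged from 4.52 to 6.96 CPM in female and from 57.3 to 107 CPM in male libraries.

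Of the 9 listed Y-linked genes 5 were kept by the low-count filter. Of these, 4 were higher in male nerves both over all genes and adjusted over the list alone. They were Kdm5d (log2 fold change -5.02), Uty (-4.59), Eif2s3y (-9.77) and Ddx3y (-10.39). Uba1y, at 0.131 ± 0.0588 CPM in females and 0.192 ± 0.0181 CPM in males, did not pass. A Y-linked long noncoding RNA with no name beyond its clone number, chosen after its values were seen, also passed; it had no reads in any female library and was at least 146-fold higher in males, against 3 reads over the 3 female libraries. Of 12 X-linked genes that escape inactivation, 2 were higher in females over all genes, the histone demethylase Kdm6a (0.74) and the translation factor Eif2s3x (0.61). Adjusted over the list alone, 8 were higher and 1 was lower. The 8 were these 2 with Xist, Jpx (0.38), Kdm5c (0.46), Ddx3x (0.48), Pbdc1 (0.35) and 5530601H04Rik (0.60), and the lower one was Mid1 (-0.78, adjusted p 0.245 by edgeR over all genes). Ftx (-0.12), Car5b (0.23) and Shroom4 (0.23) did not pass either way. Xist itself, the RNA that silences 1 X chromosome, had an edgeR adjusted p of 0.114 with a log2 fold change of 9.05; male 1 held 264 Xist reads and males 2 and 3 held 14 and 23. Its adjusted p was 2.36e-05 by edgeR without male 1, 4.58e-05 without female 2 and male 1, 0.0282 without robust estimation, 0.0357 with the muscle covariate and 3.80e-13 by DESeq2, so that it missed the threshold by a choice of the fit as well.

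**Figure D2:**
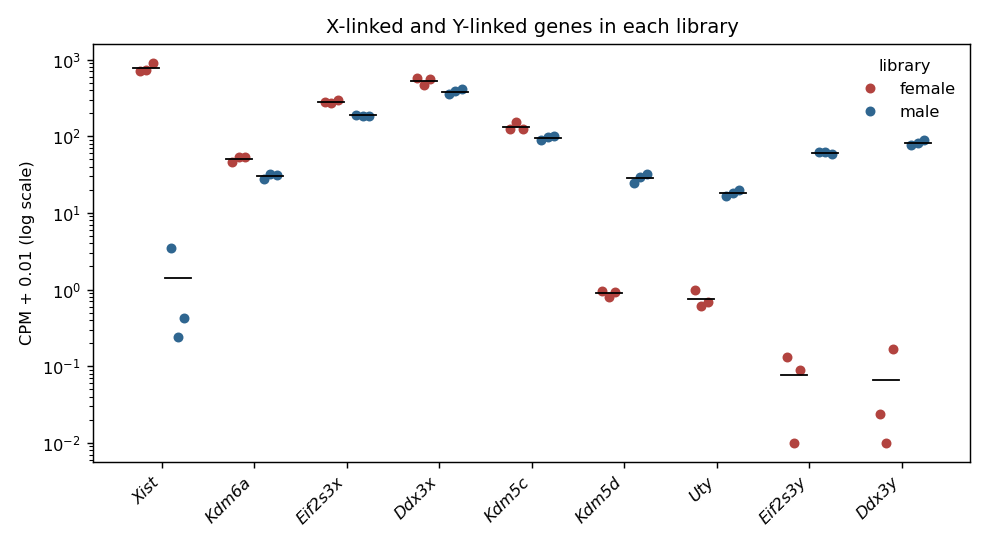
CPM plus 0.01 (log scale) of X-linked and Y-linked genes in each library (points), with group means (lines). Xist lay above 700 CPM in the female libraries and at 3.51, 0.232 and 0.416 CPM in males 1 to 3, while Eif2s3y and Ddx3y were below 0.2 CPM in every female library.

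All 19 members of the list for myelin and myelinating Schwann cells had a log2 fold change below 0, with a median of -0.73. Of these, 16 had every female library below every male one, where chance gives 5% of single genes in that direction. The members move together (estimated inter-gene correlation 0.737), so the 16 do not count as separate observations. None passed over all genes and 15 passed adjusted over the list alone. Mbp, which encodes myelin basic protein, was at 3380 ± 746 CPM in females and 6197 ± 1040 CPM in males (log2 fold change -0.87). Cnp (-0.66) and Pllp (-0.94) lay in the same direction. The list was called with the preset correlation (camera adjusted p 1.81e-12) and not with an estimated one (adjusted p = 0.513) or with fry (adjusted p 0.256). The list took 1.77%, 1.53% and 2.33% of reads in females 1 to 3 and 3.81%, 2.90% and 2.89% in males 1 to 3. Female 2 and male 1, its lowest and highest libraries, also held skeletal muscle transcripts, at 0.230% and 0.117% of reads against 0.00270% to 0.00503% in the other libraries, and without both the median was -0.48.

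**Figure D3:**
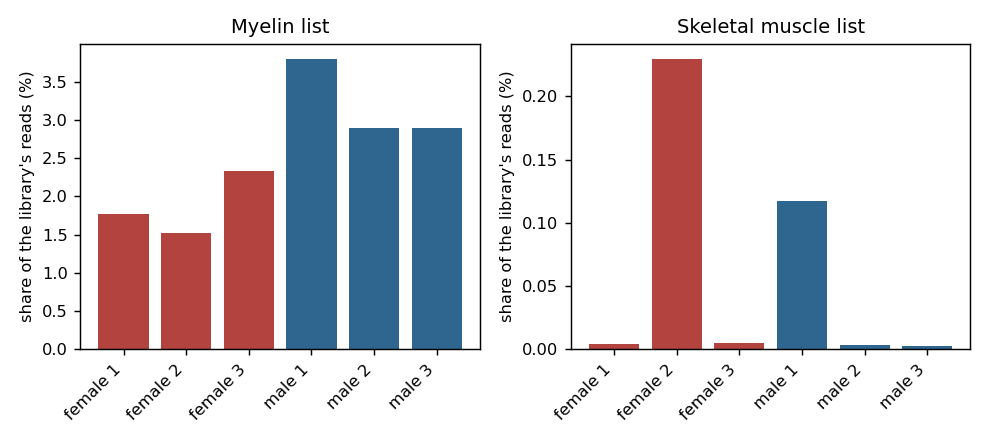
Share of each library's reads (%) that fell on the myelin list and on the skeletal muscle list (bars, 1 per library). Myelin shares ran from 1.53% to 2.33% in female and from 2.89% to 3.81% in male libraries, and muscle shares were highest in female 2 (0.230%) and male 1 (0.117%).

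The general Schwann cell list had a median of -0.27, with 12 of 13 members below 0 and 2 past the threshold adjusted over the list alone, the calcium-binding protein gene S100b (-0.83) and Art3 (-0.59). Sox10, the Schwann cell lineage factor, was at 182 ± 20.1 CPM in females and 234 ± 38.8 CPM in males, and Gpm6b had -0.51. The median was -0.16, -0.44 and -0.15 without female 2, female 3 and male 1. Genes of cholesterol synthesis, which supplies myelin membranes, were below 0 for 24 of 25 members (median -0.26), with Hsd17b7 at -0.41 and Tm7sf2 at -0.55. None passed adjusted over the list alone, and the median was -0.16 without female 2 and -0.17 without male 1. Fatty acid synthesis had a median of -0.25, with Me1 (-0.32) and Elovl6 (-0.61) past the threshold adjusted over the list alone, and Fasn (-0.25) and Scd2 (-0.49) not; its median was -0.12 without male 1. All 3 lists were called higher in male nerves with the preset correlation and not with an estimated one (adjusted p = 0.513 for each). With female 2 and male 1 both left out, the general Schwann cell list was no longer called (adjusted p 0.126 by camera).

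Of 10 genes of antigen presentation by MHC class II, 9 had a log2 fold change below 0, with a median of -0.45. H2-DMb1 (-0.66, edgeR adjusted p 0.0105) and H2-DMa (-0.63, edgeR adjusted p 0.0166) passed over all genes, and these with Cd74 (-0.56), H2-Aa (-0.45) and H2-Ab1, the last chosen after its values were seen, passed adjusted over the list alone. Without female 2 and male 1 the median was -0.68. The T and NK cell list had a median of -0.67, and 8 members were lower and 1 was higher in females adjusted over the list alone. The lower ones included Klrb1c (-1.08), Trbc1 (-1.26), Lck (-0.86) and Cd3g (-1.06), each with a mean below 4 CPM in both sexes, and the higher one was the cytokine receptor gene Il7r, chosen after its values were seen (0.92, at 33.0 ± 12.3 against 17.5 ± 2.87 CPM). In the B cell list 9 of 12 members were below 0 (median -0.43), 1 of them, Ighm (-0.45), past the threshold adjusted over the list alone; Cd79a (-0.80), Blk (-1.05) and Ighd (-0.46) did not pass. With a filter at a mean CPM of 1, which left 3 members, the B cell median was 0.07 and the list was no longer called (adjusted p 0.781 by camera), nor was it called without female 2 and male 1 (adjusted p 0.107 by camera) or with the replicate block (0.0558). These 3 lists were called higher in male nerves with the preset correlation and not with an estimated one (adjusted p = 0.513 for each).

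Markers of nerve fibroblasts were below 0 for 14 of 16 members, with a median of -0.41. The collagen I genes Col1a1 (-0.85) and Col1a2 (-0.71) and the homeobox gene Meox1 (-0.78) passed adjusted over the list alone, while Dcn had -0.43. Without female 1 the median was -0.24. All 9 perineurial cell markers were below 0 (median -0.29), with Crabp2 (-0.47) and Lypd2 (-0.68) past the threshold adjusted over the list alone and Itgb4 (-0.32) and Moxd1 (-0.33) not. The perineurial median was -0.44 without female 3, and the list was no longer called without female 2 and male 1 (median -0.16). Both lists were called higher in male nerves with the preset correlation and not with an estimated one (adjusted p = 0.513 for each).

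On the female side, all 27 cell cycle genes had a log2 fold change above 0, with a median of 0.43, and 16 had every female library above every male one. None passed adjusted over the list alone; Aurka had 0.75, Cdk1 0.58, Ccna2 0.43 and Mcm7 0.21. The median was 0.24 without male 1. Cell cycle members move together (estimated inter-gene correlation 0.424), so the 16 do not count as separate observations. In the called lists other than myelin and cell cycle, fewer members were fully separated in the list's direction. Their number ran from 1 of 24 for interferon response to 13 of 25 for cholesterol synthesis. Of 16 neutrophil markers 15 were above 0 (median 0.53), and the collagenase gene Mmp8 (0.93) passed adjusted over the list alone. Csf3r (0.63), Il1r2 (0.50) and Mmp9 (0.77) did not, and the median was 0.34 without male 3. Both lists were called higher in female nerves with the preset correlation and not with an estimated one (adjusted p = 0.513 for each). The interferon response list was also called (median 0.29, 23 of 24 members above 0), but not with an estimated correlation (adjusted p = 0.903), and its median was -0.09 without female 2. Rsad2 stood at 253 CPM in female 2 and at 117 and 124 CPM in females 1 and 3, against 81.9 to 98.5 CPM in males. Oasl1 (0.60), Cmpk2 (0.65) and Rtp4 (0.30) were also highest in female 2, the library with the largest shares of muscle and of adipocyte transcripts (0.218% for the latter, against 0.0692% to 0.130% elsewhere). The median was 0.44 without female 3. The list was no longer called without female 2 (camera adjusted p 0.335), without male 2, or without female 2 and male 1.

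**Figure D4:**
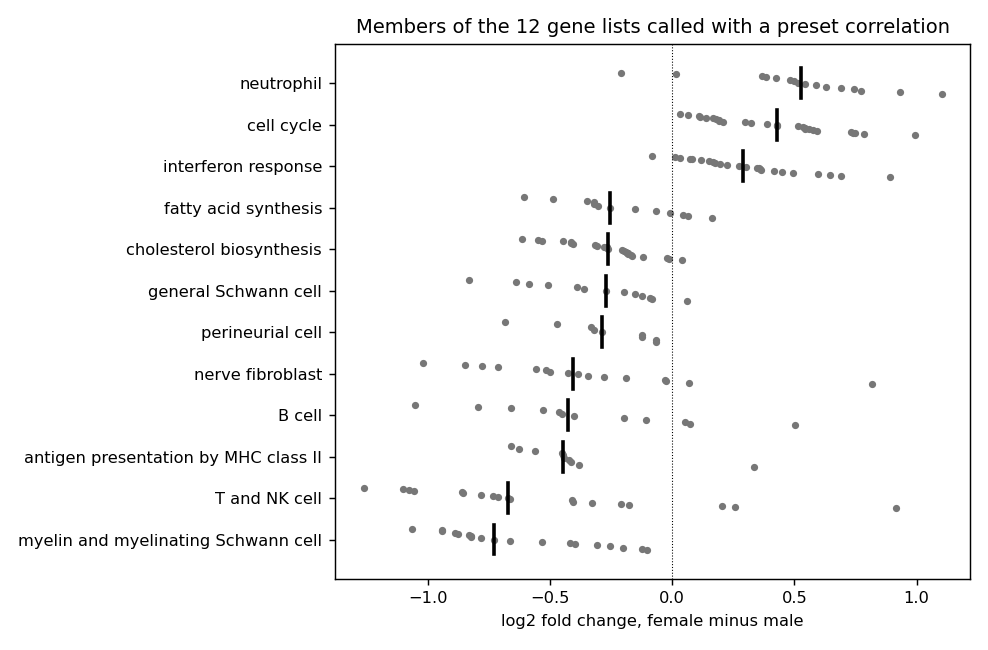
Log2 fold changes (female minus male) of the members of the 12 lists called with the preset correlation, each point a gene and each line the list's median. Myelin genes lay below 0 throughout, with a median of -0.73, and cell cycle genes above 0, with a median of 0.43.

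The reference genes of the injury response did not pass the threshold in either direction. Atf3 and Jun, transcription factors of the injury response, were at 71.1 ± 13.7 and 177 ± 19.8 CPM in females and at 59.3 ± 5.17 and 174 ± 8.25 CPM in males. Gdnf was at 88.0 ± 5.30 against 77.3 ± 10.9 CPM, and Shh at 283 ± 42.8 against 259 ± 11.8 CPM. The chemokine gene Ccl2 was at 355 ± 13.9 CPM in females and 312 ± 31.6 CPM in males, and Il1b at 197 ± 43.2 and 151 ± 60.8 CPM. Adgre1, a macrophage marker, was at 200.2 ± 48.5 against 156 ± 53.4 CPM, and the neutrophil marker S100a8 at 299 ± 129 against 214 ± 90.8 CPM. The estrogen receptor gene Esr1 was at 9.51 ± 3.03 CPM in females and 9.13 ± 1.32 CPM in males. Adipoq was at 55.5 ± 38.9 against 49.9 ± 16.2 CPM. Acta1, a skeletal muscle actin, was at 111 ± 187 CPM in females and 42.8 ± 73.1 CPM in males. That these genes did not pass does not show that their levels are equal.

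Of the lists that were not called, the matrix proteases and their inhibitors (median -0.08, mean 0.12) and the circadian clock (median -0.01) held members that moved both ways. Of the former, 3 members were higher and 4 lower in females adjusted over the list alone, and of the clock genes 3 and 2. In the list of cytokines and chemokines (median 0.17) 1 member passed adjusted over the list alone, Cxcl14 (-0.78), chosen after its values were seen. No member passed in the other uncalled lists. Their medians were -0.13 for immediate early genes, -0.06 for injury-induced Schwann cell genes, 0.17 for monocytes and macrophages, 0.44 for adipocytes, 0.81 for skeletal muscle, 0.01 for mural cells, -0.21 for mast cells and 0.11 for endothelial cells. They were -0.04 for the glucocorticoid response, -0.08 for heat shock genes, -0.08 for mitochondrially encoded RNA, 0.04 for red blood cells, and 0.06 for hormone receptors and steroid enzymes. The median was 0.16 for the 2 keratinocyte genes kept by the low-count filter. The mural cell and red blood cell lists had a positive median and a camera direction toward male nerves, as did the hormone receptor list.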

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

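In this part the tests of Schwann cell share, of muscle as the whole cause, of paralog reads and of clock genes near Nr1d1, and the counts of splits for genes and lists, were chosen only after the result was seen.

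A signal in data outside the main comparison drew attention: reads assigned to the transcript Uty-212 of a Y-linked gene averaged 54.2 in the 3 female libraries, where 3 reads is the limit a count of 0 allows. Female libraries 1 to 3 held 69.0, 41.3 and 52.2 such reads, and males held 51.5, 59.5 and 53.9. This transcript made up 95.8% to 100% of Uty reads in females and 4.09% to 5.43% in males. The female level behind the Uty log2 fold change of -4.59 thus rests almost wholly on these reads. A BLAST search on the same strand found no match of Uty-212 to Kdm6a-201, a transcript of the X-linked Kdm6a, and the source of the reads was not found.

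Myelin genes had a median log2 fold change of -0.73 in female against male nerves. The median difference of log2 CPM was -0.74 for the sexes and at most 0.60 in size in the other splits of the 6 libraries into 3 and 3; 1 of 10 splits, the real one, was as large, and 10 splits are too few for a share under 0.05. As the pattern was taken up for its size, this decides nothing. A smaller share of all Schwann cells alike would lower the general Schwann cell list by as much. The gap between the lists differed by -0.31 with a pooled SD of 0.07, which argues against that as the whole cause. Members of the general list ran from -0.83 to 0.06, so the list is an uneven measure of that share. A smaller share of myelinating Schwann cells alone was not tested and stays open. A few abundant genes taking more of the counts in female libraries is argued against by their shares, read after the result. The 100 most abundant genes of each library took 17.5% to 17.8% of reads in females and 18.5% to 20.2% in males. TMM factors ran from 0.968 to 1.02, and the median log2 fold change of all genes was 0.016. Leaving the 100 most abundant genes out of the scaling gave -0.73, but the scaling hardly changed, so that fit decides nothing. The bound set beforehand took no account of this, and the rule that a scaling which changes too little decides nothing was added after the value was seen. Skeletal muscle in female 2 and male 1 is only weakly argued against as the whole cause. In the other 4 libraries both female scores of the list lay below both male ones, with a difference of -0.39 and a pooled SD of 0.18. With so few libraries per sex, such a separation can arise by chance. With muscle level as a covariate the median was -0.73. Whether muscle adds to the size cannot be told apart from a sex difference. The median without both libraries was -0.48, between the bounds set for either answer. A lower level of myelin transcripts in female nerves stays open as a hypothesis, as do the surgery and dissection of each pool.

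Rdh9 and Rdh16f1 were chosen after their values were seen. Rdh9 was higher in male nerves, while Rdh16f1 was at least 26.4-fold higher in females, against 3 reads over the males, whose libraries were all at 0, but did not pass the threshold (edgeR adjusted p 0.0702). The transcripts of both genes that held these reads are 99.5% identical over 2620 nt, and their summed RPM values were 0.412 ± 0.112 in females and 0.509 ± 0.0579 in males, overlapping, with a log2 ratio of -0.30. This fits an assignment of the same reads to either paralog, as a candidate explanation. A sequence difference between the female and the male mice cannot be told apart from it: 54 autosomal transcripts were all-or-none by sex and up to 79 in another split, but a difference at a single locus needs no excess over the genome, so the bound set beforehand was wrong.

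The clock genes below were chosen after their values were seen. Per2 (0.49), Cry1 (0.43) and Hlf (0.33) were higher and Arntl (-0.50) and Nr1d1 (-0.89) lower in female nerves, adjusted over the list alone. The mean absolute difference of the list was 0.26 for the sexes and at most 0.19 in the other splits, with 1 of 10 as large, again too few for a share under 0.05. As the pattern was taken up after these members were seen to pass, this decides nothing. Collection of the sexes at different times of the morning may be the cause, but of Dbp (-0.25, SE 0.16), Nr1d2 (0.01, SE 0.08) and Ciart (-0.02, SE 0.18), which peak close to Nr1d1, 0 were lower in females by more than 2 SE, and none was higher by as much. The hour of collection per library is not given in the sources used here, so this cannot be told apart from a sex difference.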

How the results depend on the processing

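The alternatives without the muscle libraries, with a muscle covariate and without robust estimation were chosen after seeing the data. The cause of the changes below was not tested, except that fewer libraries or genes were used where stated. Counts are given as genes higher in female and in male nerves, then the autosomal ones.

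With no low-count filter the counts were 44 and 147 (39 and 138); with a mean CPM of at least 1 the autosomal counts were 0 and 8. DESeq2 gave 216 and 623 (204 and 599). limma-voom gave 7 higher in female nerves (4 autosomal), limma on log2(TPM + 1) gave 1 and 9 (0 and 3), and a minimum of 1.2-fold gave 0 higher in female nerves (0 and 7 autosomal). Leaving out 1 library gave 0 to 17 and 4 to 188 (0 to 15 and 0 to 178), with both highest values without female 3. Without female 2 and male 1 the counts were 6 higher in female nerves (5 and 8 autosomal), and 10 of the 21 genes were shared. The muscle covariate gave 11 higher in male nerves (6 autosomal), and edgeR without robust estimation gave 0 autosomal genes higher in female nerves. At an unadjusted p under 0.05, edgeR counted 2784 genes. No scaling moved the median of all genes by 0.01.

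The replicate block gave 0 and 3 genes (0 and 1 autosomal), and Adipoq had -0.057 with it. After the mean of each sex was taken off, the deviations of libraries with the same replicate number had correlations of -0.10, -0.19 and 0.01. These give no sign that the numbers pair the libraries, but so few values cannot exclude it. Among the lists, the replicate block ended the B cell call (adjusted p 0.0558 by camera) and added those of immediate early genes and of monocytes and macrophages (0.0325 each).

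The number of lists was 3 higher in female and 9 higher in male nerves; leaving out 1 library gave 2 to 5 and 9 to 13. Without female 2 and male 1 the preset correlation gave 4 and 8: the interferon, B cell, general Schwann cell and perineurial calls ended, while the skeletal muscle and cytokine lists were added as higher in female and the mast and mural cell lists as higher in male nerves. An estimated correlation gave 0 and 0, as did fry's test for a shift in 1 direction. Leaving out the muscle libraries with an estimated correlation gave 0 and 0. Fry's mixed test, which counts members moving either way, was not adjusted over the lists. Its p was 3.57e-06 for the circadian clock, 0.000353 for injury-induced Schwann cell genes and 0.000820 for matrix proteases. In the other uncalled lists it was at least 0.207. Among called lists it was lowest for MHC class II (3.51e-05) and above 0.05 for cholesterol synthesis, general Schwann cells, neutrophils and interferon response.

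The single genes that turned direction had not passed the threshold, while the interferon and B cell lists had been called. Leaving out 1 library gave Jun -0.080 to 0.072, Adipoq -0.57 to 0.50, Acta1 -3.95 to 7.50, Esr1 -0.23 to 0.23 and the interferon list -0.086 to 0.44. Without female 2 and male 1, Ftx had 0.063, Car5b -0.0067, Jun -0.060, Adgre1 -0.10, Adipoq -0.69, Esr1 -0.32 and the interferon list -0.10. With the muscle covariate Jun had -0.0033, Adipoq -0.16 and Esr1 -0.014. The B cell list had 0.072 at a mean CPM of at least 1. Every alternative compared gene by gene, which both limma fits and the 1.2-fold minimum were not, kept the direction of the genes past the threshold that the text names by rule.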

Other observations

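The gene families in this part were chosen after their values were seen, so each is a hypothesis. Of 42 collagen genes kept by the low-count filter, 36 had a log2 fold change below 0 (female minus male), with a median of -0.45. In this family 20 passed adjusted over the family alone but none over all genes, and Col5a1 had -0.45. Of 14 small leucine-rich proteoglycans, which bind collagen, 11 were below 0, 6 passed over the family alone and 1, Fmod, over all genes; the 6 include Prelp (-0.55) and Ogn (-0.57), while Aspn had 0.15. Of 22 genes with a symbol of the killer cell lectin-like receptors, pseudogenes included, 19 were below 0 and 6, among them the pseudogene Klra13-ps, passed over the family alone but none over all genes, with Klra8 at 0.587 ± 0.102 CPM in females and 1.64 ± 0.271 CPM in males. These genes are alike in sequence, so their single levels are uncertain. Of 60 genes with a Kcn symbol, most of them for potassium channels but with noncoding RNAs and a regulator among them, 34 were below and 26 above 0 (median -0.05), and 4 passed over the family alone, among them Kcna1 (-1.04) and Kcnt1 (-2.55); the median was matched by 4 of 10 splits, the real one included. The matrix protease list was not called (camera adjusted p 0.732). The members past the threshold over the list alone were Mmp12 (1.74), Mmp13 (1.35) and Adam8 (0.65), higher in females, and Timp2 (-0.48), Mmp2 (-0.34), Plat (-0.32) and Adamts5 (-0.38), lower.

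The sexes were compared with the other splits of the 6 libraries. The collagen median differed by -0.45 between the sexes and by at most 0.27 in other splits, and the lectin-like receptor median by -0.59 and at most 0.44, with 1 of 10 splits as large for each; as both families were chosen for this difference, this decides nothing. Among the 12 called lists, the median of the interferon list was matched by 5 of 10 splits, the real one included, that of the general Schwann cell list by 3, and those of MHC class II, cholesterol synthesis and neutrophils by 2 each. For the other called lists the real split alone was as large. The sexes gave 21 genes and 14 autosomal genes past the threshold, and no other split gave any (0 by edgeR, with up to 1196 genes at an unadjusted p under 0.05), so 1 of 10 was as large. Each other split put both sexes in both groups. Sex-linked genes could thus hardly pass there, and any sex difference widened the spread within groups, so the 0 decides nothing. The 12 lists called with the preset correlation were matched by 7 of 10 splits, the real one included, with up to 17 in another split. With 10 splits no share can be under 0.05.

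Gm7334, a pseudogene identical over its 756 nt to part of Btg3, was chosen after its values were seen; it was at least 58.8-fold higher in females, against 3 reads over the males, with an edgeR adjusted p of 0.0516. Kdm5d reads in female libraries were 2.81% to 3.35% of the male mean, against at most 0.197% for Ddx3y. Xist in male 1 was 0.432% of the female mean. This was 1 of 2 tests on those Xist reads that were run and then set aside; the other followed a muscle transcript that male 1 held by itself, with 24990 reads there, and so decided nothing. Keratinocyte transcripts took 0.00446% of reads in female 1 and at most 0.000403% elsewhere.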
